A study of Mus musculus with 10 samples.

How the data were processed

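The series holds 10 RNA sequencing libraries from the colon of male C57BL/6 mice in a chemical model of colitis-associated colorectal cancer, in which azoxymethane (AOM), a mutagen, is followed by cycles of dextran sulfate sodium (DSS), which injures the colonic epithelium. Per the labels, AOM was given at 12.5 mg/kg to mice of 7 weeks and 18 to 20 g, followed by 3 cycles of 3 weeks, each with 5 days of 2% DSS and 16 days of water. Tissue was taken 10 weeks after AOM. The labels count 15 mice, 12 treated and 3 untreated, and none of the 10 libraries is labelled as from an untreated mouse. The sample type label sets the groups, 5 tumours and 5 samples of adjacent tissue, and the titles number each group 1 to 5. The source label names the same mouse for all 10 libraries, while the series text speaks of several mice, so the labels do not settle which libraries share an animal. The p-values therefore measure the spread between these samples, which may be less than that between animals.

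Per the labels' protocols, polyadenylated RNA was selected with oligo-dT, libraries were made with the TruSeq RNA v2 kit, and they were sequenced on an Illumina HiSeq. The submitters' processing notes name TopHat2 2.1.0, Cufflinks 2.2.1, RSEM 1.2.15, Salmon 0.8.2, edgeR 3.16.5, DESeq2 1.14.1, GATK and the mouse build mm10, without saying which of them made the expression table. The deposited table gives FPKM, fragments normalized to transcript length and to the total mapped, for 24525 gene symbols in each library, as the authors computed them. One line of the table holds text in place of values and was left out. Of the genes, 4792 were at 0 in every library, and none of the mitochondrially encoded genes of the fixed list was in the table. FPKM divides by each library's total, so a gene's value also depends on how much the other genes take. The protein data of the series were not used here.

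Depth is not stated in the table and was estimated from the steps between low values of genes with 1 annotated transcript length, which are multiples of what 1 fragment is worth. This gave 22700000 to 28400000 fragments per library as a rough value, from 30 to 52 low values in each. On average over the libraries, 83.8% of those values (75.6% to 96.8%) lay within 0.2 of a whole number of fragments, against at most 63.8% in 10 repeats with the lengths shuffled among genes. No counting interval was computed. Between any pair of libraries at least 17741 genes differed, so no library was a copy of another. Of the genes in the table, 17 had values identical to those of another gene in all libraries, and 7 were at 0 in at least 1 library and over 20 FPKM in another, among them Defa36 and Hba-a2. Some belong to families of similar genes, such as the defensins and globins, and how reads were split among such genes is not given in the sources used here.

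The design fixed before the data were examined had a count test for a table of counts, and limma for a table of FPKM. The table holds FPKM, so limma 3.58.1 in R 4.3.3 was fitted to log2(FPKM + 1) with group as the only term, with an intensity trend and robust empirical Bayes, over the 13016 genes with a mean of at least 1 FPKM over all libraries. Tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, tumour minus adjacent, and this scale understates the change of low genes. Means and SDs are of FPKM. A gene is said to have risen or fallen only if its adjusted p passed the threshold. On data simulated from each gene's mean and its spread within groups over 13016 genes, the same fit called 0 genes where none was changed. With 200 genes changed it made 169 calls, 8 of them false, and recovered 50%, 76%, 96% and 100% of the genes changed by 0.5, 1, 2 and 3 on the log2 scale. The simulation drew genes independently, with few of them changed and no shift of all genes, so these rates may not hold for the real data.

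Before the data were examined, 43 gene lists were fixed, of which 41 were tested, each with at least 3 genes past the expression filter. The list of mitochondrially encoded genes had no member in the table, and the list of sex-linked genes served only to check the labels: Xist was at most 0.04 FPKM and Ddx3y at least 12.11 FPKM in every library, as in male tissue. Lists were tested with camera of limma at a preset correlation of 0.01, again with a correlation estimated per list, and with fry. Several lists share members, such as Axin2, Prox1, Mmp7 and Kit. The genes named in the text follow a rule also fixed beforehand: the 14 largest rises and 12 largest falls among genes past the threshold that went the same way in all 5 like-numbered pairs, with a mean of at least 1 FPKM and without clone-named genes or antigen receptor segments; for each list, up to 2 members with the largest rise and up to 2 with the largest fall past the threshold, or the 2 most abundant where none passed; and a short set of textbook genes. A few genes that the rule names are not reported here. Cdx1, Cdx2, Myc, Notum, Smad4, Hoxb13, Hoxd13 and the genes of families that appear only in the closing section were chosen after their values were seen.

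The spread within groups was compared as the median over genes of the log2 ratio of the SD in tumours to that in adjacent tissue, with an exact permutation test over all 252 assignments of the 10 libraries after centring each group. Coordinates are from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names; 97.8% of the tested genes had a transcript length there. Other settings fixed beforehand were pseudocounts of 0.1 and 5, no filter and a mean of at least 5 FPKM, quantile normalization, the replicate number as a block, and leaving out each library or numbered pair in turn. Settings that need counts were not run, because the table holds none. Subtracting each library's median and leaving out tumours 2 and 4 together were added after the values were seen. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 made the remaining tables and the plots.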

Results

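Gene expression was measured by RNA sequencing of polyadenylated RNA in 5 colorectal tumours and 5 samples of adjacent colon tissue from mice given AOM and DSS, at 10 weeks after AOM. The comparison asks which genes differ between tumour and adjacent tissue in this model of colitis-associated cancer. Values are FPKM per gene, with a total of 462009 to 484712 FPKM per library over 24525 genes. Between 11981 and 13171 genes per library reached at least 1 FPKM. The depth estimated from low values was similar across libraries, at 22700000 to 28400000 fragments.

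Tumours had far lower levels of the genes of mature colonic epithelium and higher levels of Wnt target, cell cycle, matrix and inflammatory genes than adjacent tissue. Car4, a carbonic anhydrase of surface colonocytes (chromosome 11, 84957786 to 84966044, GRCm38), fell from 776 ± 147 to 11.6 ± 15.0 FPKM (SD, n = 5 per group), a log2 change of -6.52 (SE 0.53; limma adjusted p = 1.46e-05). Axin2, a feedback target of Wnt signalling (chromosome 11, 108920349 to 108950783), rose from 22.3 ± 9.57 to 120 ± 37.2 FPKM, a log2 change of 2.40 (SE 0.31; limma adjusted p = 6.64e-05). Col1a1, a chain of type I collagen, rose from 19.9 ± 8.87 to 153 ± 17.7 FPKM, and S100a9, a calcium-binding protein of neutrophils, from 18.2 ± 26.7 to 130 ± 64.7 FPKM. All 4 went the same way in 5 of 5 like-numbered pairs. The naming rule required this of Car4, Col1a1 and S100a9, but not of Axin2.

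Of 13016 genes tested with limma, 9951 (76.5%) passed an adjusted p of 0.05, and 3030 of these changed at least 2-fold (1406 with a pseudocount of 5). More rose than fell, 7442 against 2509, or 74.8% higher in tumours. This split rests on the scaling: the median tested gene was 0.35 higher in tumours on the log2 scale, and with each library's median subtracted 4486 rose and 4329 fell, 50.9% higher. Quantile normalization gave 4759 higher and 3934 lower, 54.7% higher. Changes below are therefore to be read with this shift in mind, but 0.35 is a median and does not hold for every gene. Ctnnb1, an abundant gene at 0.55, was at 0.22 with medians subtracted and at 0.77 with quantile normalization. Axin2, at 2.40, was at 2.07 and 2.34. For each gene list the counts with medians subtracted are given where they differ by more than 1 gene. The first principal component separated the groups and held 80.1% of the variance; tumours lay at 28.1 to 68.3 and adjacent samples at -39.6 to -70.7. Tumour 2, at 28.1, and tumour 4, at 42.6, lay closest to adjacent tissue.

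The largest rises by the fixed rule began with Hp, the haemoglobin-binding acute-phase protein haptoglobin, at a log2 change of 3.90 (SE 0.50, from 5.09 ± 5.63 to 69.8 ± 22.6 FPKM, n = 5 per group, limma adjusted p = 7.25e-05), and Spp1, the secreted phosphoprotein osteopontin, at 3.69 (SE 0.50, limma adjusted p = 9.19e-05). The stromelysin gene Mmp10 rose by 3.46 (SE 0.67), and the collagenase gene Mmp13 from 6.28 ± 8.02 to 61.4 ± 56.0 FPKM. Alox12, a lipoxygenase, rose by 3.40 (SE 0.53), although tumour 2, at 10.3 FPKM, lay near adjacent sample 5, at 9.99 FPKM. Sox17, an endoderm and endothelial transcription factor, rose by 3.14 (SE 0.50), and Stra6, a receptor for retinol-binding protein, by 2.99 (SE 0.39). The acute-phase and antimicrobial genes Saa3 and Lcn2 rose by 3.05 (SE 0.35) and 3.04 (SE 0.45), the matrix genes Fn1 and Col1a1 by 3.02 (SE 0.34) and 3.00 (SE 0.29), S100a9 by 3.41 (SE 0.70; 4.07 without adjacent sample 5), and LOC106557447 by 3.02 (SE 0.47). Defa36, a defensin gene with near-identical copies, rose by 3.43 (SE 1.29, limma adjusted p = 0.0319) but is uncertain: it was at 0 in adjacent sample 4 and at 115 FPKM in adjacent sample 5, and its adjusted p was 0.0502 with medians subtracted. Without adjacent sample 2 or 4, or tumour 1, 3 or 5, its adjusted p was 0.0731, 0.0705, 0.0596, 0.0524 and 0.0631, with log2 changes of 2.60, 2.55, 3.32, 3.48 and 3.29; without adjacent sample 1 or 5 the change was 4.03 or 4.26, and it passed.

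Of the 12 largest falls by the fixed rule, 5 were in the absorptive colonocyte list, 2 in the goblet cell list and 1 in the enteroendocrine list; 2, Cyp2c55 and Ces2c, were in the drug and xenobiotic metabolism list. After Car4 came Cyp2c55, a cytochrome P450 enzyme, which fell by 6.51 on the log2 scale (SE 0.47, from 246 ± 148 to 1.49 ± 1.16 FPKM, n = 5 per group, limma adjusted p = 1.06e-05), the water channel Aqp8, which fell by 6.48 (SE 0.49), and the chloride-bicarbonate exchanger Slc26a3, which fell by 5.87 (SE 0.50). Mptx1, a pentraxin, fell by 5.32 (SE 0.99), and Sycn, a secretory granule protein, fell by 5.16 (SE 0.54). Ces2c, a carboxylesterase, fell by 5.01 (SE 0.45), and the enteroendocrine hormone gene Insl5 fell by 4.98 (SE 0.61). Hao2, a peroxisomal hydroxyacid oxidase, fell by 4.98 (SE 0.47), the goblet cell genes Clca1 and Zg16 by 4.95 (SE 0.58) and 4.77 (SE 0.57), and the fatty acid binding protein Fabp2 by 4.63 (SE 0.71). For all 12 the limma adjusted p was 0.00066 or lower. Tumour 4 kept the highest tumour levels of Car4, Aqp8, Sycn, Hao2 and Zg16, at 38.2, 12.9, 63.4, 15.5 and 899 FPKM, below every adjacent sample. Without tumour 4 the log2 change of Zg16 was -5.38, and without adjacent sample 4 that of Mptx1 was -4.61.

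**Figure D1:**
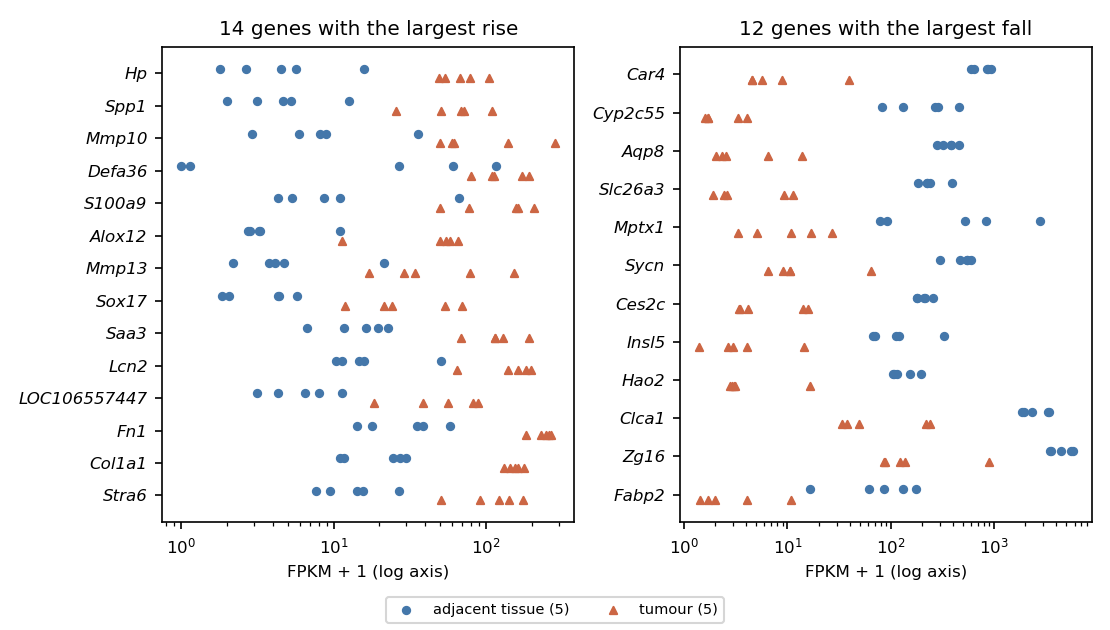
FPKM + 1 on a log axis for the 14 genes with the largest rise and the 12 with the largest fall, with 1 circle for each of 5 adjacent samples and 1 triangle for each of 5 tumours. Tumour and adjacent values of Car4 are far apart, 776 against 11.6 FPKM on average, while single libraries of the groups overlap for Mmp13, S100a9 and Defa36.

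All 23 Wnt and beta-catenin target genes rose, with a median log2 change of 2.11, and 22 did so with medians subtracted. Prox1, a transcription factor, rose by 2.87 (SE 0.32) and Nkd1, a Wnt antagonist, by 2.81 (SE 0.30). Notum, which removes the lipid of Wnt proteins, rose by 2.62 (SE 0.33), and Myc by 1.28 (SE 0.11). Of 13 intestinal stem cell genes, 10 rose and 1 fell, with a median of 1.23; with medians subtracted 8 rose and 3 fell. Lgr5, a stem cell receptor, rose, by 1.76 with medians subtracted (adjusted p = 0.000253), and Tnfrsf19 rose by 2.14 (SE 0.27). Lrig1 fell by 0.27 (SE 0.10, limma adjusted p = 0.0366), with a log2 change of -0.60 with medians subtracted (adjusted p = 0.000399) and -0.46 with quantile normalization (adjusted p = 0.00288). Without either scaling the Lrig1 call was lost with the replicate block (adjusted p = 0.0976) and without any one of adjacent samples 1, 3, 4 and 5 or tumours 1, 3 and 5 (adjusted p from 0.0505 to 0.0895). Of 17 genes of the fetal-like and regenerative epithelium, 12 rose and 3 fell, with a median of 1.41; with medians subtracted the counts were 10 and 3. Anxa3 fell by 0.94 (SE 0.19), and Areg, a ligand of the EGF receptor, fell by 1.10 (SE 0.45, limma adjusted p = 0.0467), which was lost without any one of the libraries but tumours 2 and 4 (8 of 10 fits, adjusted p from 0.0528 to 0.108).

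Most genes of colonocytes, goblet cells and enteroendocrine cells fell. Of 26 absorptive colonocyte genes 24 fell and none rose, with a median log2 change of -2.91. Of 16 goblet cell genes 15 fell and none rose, with a median of -2.16. The counts were the same with medians subtracted. Tumours 2 and 4 lay nearest to adjacent tissue: their means of the absorptive colonocyte list were 5.44 and 5.10 on the log2(FPKM + 1) scale, against 3.86 to 3.92 in the other 3 tumours and 7.22 to 7.66 in adjacent samples. For the goblet cell list they were 7.04 and 6.63, against 5.21 to 5.64 in the other 3. The lowest mean of the enteroendocrine list, 0.78, was in tumour 2. Muc2, the main gel-forming mucin of goblet cells, fell from 1353 ± 330 to 231 ± 179 FPKM (n = 5 per group), a log2 change of -2.87 (SE 0.48), and Krt20, a keratin of mature cells, by 3.18 (SE 0.80). Krt20 was at 434 FPKM in tumour 2, above the 388 FPKM of adjacent sample 5, and its log2 change was -3.86 without tumour 2. The intestinal identity factors Cdx1 and Cdx2 fell by 1.58 (SE 0.17) and 3.06 (SE 0.75). Of 13 enteroendocrine genes, 11 fell and 1 rose, with a median of -2.29: Gcg, the proglucagon gene, fell by 4.12 (SE 0.33), and Isl1, a transcription factor, rose by 1.86 (SE 0.57). Of 6 tuft cell genes, Avil and Ptgs1 rose by 2.63 (SE 0.34) and 1.40 (SE 0.16), while Trpm5 and Dclk1 fell by 1.30 (SE 0.23) and 0.57 (SE 0.23), with 3 falls in all. The tuft cell genes Pou2f3, Gfi1b, Il25, Chat and Siglecf were below the expression filter, and each had a lower mean in tumours. With no filter the tuft cell list had a median of -0.22 and passed with camera (adjusted p = 0.0229). The Dclk1 call was lost without any one of the libraries but adjacent sample 5 and tumour 2 (8 of 10 fits, adjusted p from 0.0589 to 0.0886). Of 16 Paneth-like and antimicrobial genes, 7 rose and 5 fell: Mmp7, matrilysin, rose by 2.50 (SE 0.47), while the acute-phase genes Saa1 and Saa2 fell by 3.50 (SE 0.53) and 3.12 (SE 0.39). Of 6 genes of small-intestinal and proximal identity, 4 fell and 1 rose, with a median of -1.67; Mep1a, a brush border protease, fell by 4.30 (SE 0.42), Alpi, intestinal alkaline phosphatase, by 2.04 (SE 0.28), and Onecut2 rose by 2.21 (SE 0.66). Cdh1, E-cadherin, fell by 0.49 (SE 0.09).

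Of 28 cell cycle genes 27 rose, with a median log2 change of 1.33, among them Top2a, topoisomerase II alpha, by 1.66 (SE 0.17) and the replication helicase gene Mcm3 by 1.58 (SE 0.14). Mki67, a proliferation marker, rose from 19.9 ± 2.44 to 40.0 ± 7.18 FPKM (n = 5 per group). All 20 ribosome biogenesis genes rose, with a median of 0.98, and did so with medians subtracted; the nucleolar genes Nop56 and Mybbp1a rose by 1.31 (SE 0.16) and 1.28 (SE 0.13). Of 20 translation factor genes 18 rose and 2 fell, with a median of 0.60, but with medians subtracted 10 rose and 2 fell. The median of the list was 0.27 with medians subtracted and 0.55 with quantile normalization. Pabpc1 and Eif4a1 rose by 1.04 (SE 0.17) and 0.94 (SE 0.10), and Eif2s2 and Eif6 fell by 0.83 (SE 0.22) and 0.60 (SE 0.08). Of 18 mismatch repair and DNA repair genes 17 rose, with a median of 0.89; Pole, a DNA polymerase subunit, rose by 1.55 (SE 0.24) and Parp1 by 1.43 (SE 0.13). Mgmt, which removes alkyl groups from guanine and so repairs AOM adducts, did not pass, at 1.95 ± 0.22 and 1.49 ± 0.66 FPKM (log2 change -0.28, SE 0.17, limma adjusted p = 0.151); it passed with medians subtracted (-0.61, adjusted p = 0.00768), with quantile normalization (-0.73, adjusted p = 0.00133) and without tumour 5 (-0.39, adjusted p = 0.0467).

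All 19 fibroblast and extracellular matrix genes rose, with a median log2 change of 2.22, as did all 16 matrix metalloproteinases and inhibitors, with a median of 2.08, and all 14 endothelial genes, with a median of 1.27. Fn1, fibronectin, rose from 31.9 ± 17.7 to 236 ± 33.6 FPKM (n = 5 per group), and Cdh5, the cadherin of endothelial junctions, rose by 1.87 (SE 0.18). Of 13 smooth muscle genes 8 rose and none fell, with a median of 0.61, but 4 rose with medians subtracted; Acta2 and Actg2, actins of smooth muscle, rose by 1.74 (SE 0.27) and 1.51 (SE 0.35). Myh11, smooth muscle myosin, did not pass, at 6.79 ± 3.69 and 10.7 ± 4.41 FPKM. Of 17 TGF-beta and BMP signalling genes 14 rose and 2 fell, with a median of 1.57; with medians subtracted 12 rose. Grem1, a BMP antagonist, and Inhba, an activin subunit, rose by 2.66 (SE 0.39) and 2.59 (SE 0.28), Bmp2 fell by 0.97 (SE 0.17), and Id4 fell by 0.52 (SE 0.22, limma adjusted p = 0.0486), with -0.85 with medians subtracted (adjusted p = 0.00531) and -0.98 with quantile normalization (adjusted p = 0.000651). Without either scaling the Id4 call was lost with the replicate block (adjusted p = 0.127) and without any one of the libraries but tumours 2 and 4 (8 of 10 fits, adjusted p from 0.0523 to 0.116).

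Of 20 inflammatory cytokine and chemokine genes 18 rose and none fell, with a median log2 change of 1.96; Il11, an interleukin of the IL-6 family, rose by 2.70 (SE 0.50). Of 15 neutrophil genes 14 rose, with a median of 1.68, and 12 did so with medians subtracted; S100a8, the partner of S100a9, rose by 2.90 (SE 0.62). Adjacent sample 5 had the highest adjacent mean of the neutrophil list, 2.49 on the log2(FPKM + 1) scale against 0.72 to 1.16 in the other 4. Of 16 macrophage and monocyte genes 14 rose, with a median of 1.62; Arg1, arginase 1, and Lyz2, a lysozyme, rose by 2.09 (SE 0.42) and 2.08 (SE 0.33). Of 13 T cell genes 7 rose and none fell, with a median of 0.62, but 3 rose with medians subtracted; the receptor kinase Zap70 rose by 1.46 (SE 0.23) and Ctla4, an inhibitory receptor, by 0.90 (SE 0.23), the latter past the threshold except with quantile normalization (adjusted p = 0.0519). Of 11 immune checkpoint genes 7 rose, with a median of 0.90; Tnfrsf9 and Vsir rose by 2.06 (SE 0.19) and 1.25 (SE 0.21). Of 8 B and plasma cell genes none rose and 2 fell, among them Cd79a by 1.25 (SE 0.48). None passed the threshold when adjusted over the list alone, and 4 fell with medians subtracted. The Cd79a call was lost without any one of adjacent samples 1, 2 and 3 or tumours 1, 3, 4 and 5 (adjusted p from 0.0544 to 0.0834). Ms4a1, Tnfrsf17, Cr2, Fcer2a, Blk, Cxcr5 and Pax5 of this list were below the expression filter, and each had a lower mean in tumours. Tumour 2 had a B and plasma cell list mean of 3.37 on the log2(FPKM + 1) scale, against 1.18 to 2.21 in the other 4 tumours. Adjacent samples had means of 2.28 to 3.99. None of 10 class II antigen presentation genes passed; Cd74, the invariant chain, was at 377 ± 97.0 and 589 ± 381 FPKM, and H2-Ab1 at 121 ± 25.2 and 185 ± 128 FPKM. Tumour 2 had the highest tumour means of the T cell list, 2.55, and of the class II list, 5.45 on the log2(FPKM + 1) scale.

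Of 18 type I interferon response genes, Usp18 rose by 1.17 (SE 0.37) and 3 fell, among them Irf7 by 1.49 (SE 0.58) and Oasl1 by 1.32 (SE 0.49), with none past the threshold when adjusted over the list alone. The Usp18 call was lost with medians subtracted (adjusted p = 0.0767) and with quantile normalization (0.0611). That of Irf7 was lost without any one of adjacent samples 1, 2 and 4 or tumours 1, 3 and 5 (adjusted p from 0.0602 to 0.0875). That of Oasl1 was lost likewise except for adjacent sample 4 (0.0517 to 0.074). With the replicate block Irf7 and Oasl1 passed (limma adjusted p = 0.0041 and 0.00615), although the labels do not settle whether the numbers pair the samples. Of 8 mast cell genes Cma1, a chymase, rose by 0.99 (SE 0.41, limma adjusted p = 0.0469) and Kit fell by 1.00 (SE 0.16). The Cma1 call was lost with medians subtracted (adjusted p = 0.169), without any one of the libraries but adjacent sample 5 and tumours 2 and 3 (0.0767 to 0.108) and when adjusted over the list alone. None of 6 red blood cell genes passed; Hba-a1, a haemoglobin gene with near-identical copies, was at 73.1 ± 72.1 and 135 ± 105 FPKM, and Hbb-b1 at 46.4 ± 48.8 and 85.0 ± 69.7 FPKM, which passed without adjacent sample 5 (log2 change 1.40, adjusted p = 0.0442). Both passed with the replicate block without pair 2, at log2 changes of 1.33 (adjusted p = 0.00987) and 1.29 (adjusted p = 0.00668).

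Many markers of tissue outside the colonic mucosa were below the expression filter. Of 16 enteric neuron and glia genes 4 were tested; Tubb3 rose by 1.18 (SE 0.20), and Tac1 fell by 1.25 (SE 0.43), a call lost without any one of adjacent samples 2 and 3 or tumours 1 and 5 (adjusted p from 0.0508 to 0.0544). Of 5 genes of the interstitial cells of Cajal, the pacemaker cells of gut muscle, 3 fell and 1 rose; Thbs4, a thrombospondin, fell by 3.60 (SE 0.40) and Gucy1b3 rose by 1.10 (SE 0.19). Of 5 adipocyte genes Pck1 and Cidec fell by 4.04 (SE 0.32) and 1.26 (SE 0.26); Lipe rose by 0.50 (SE 0.09), but by 0.17 with medians subtracted (adjusted p = 0.0715). Pck1 is also a gluconeogenic enzyme of epithelium. Of 4 pancreatic acinar genes Pnliprp1 rose by 1.98 (SE 0.45) and Cela1 fell by 1.69 (SE 0.24). Of 12 squamous epithelium genes 6 were tested and 5 rose, with a median of 1.19. Krt14 and Krt15 rose by 2.13 (SE 0.24) and 2.00 (SE 0.36), while Krt5 and Trp63 were at most 0.02 and 0.03 FPKM in any library.

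Most genes of the drug metabolism, fatty acid oxidation and oxidative phosphorylation lists fell. Of 23 drug and xenobiotic metabolism genes 21 fell and none rose, with a median log2 change of -3.09. Cyp2e1, a cytochrome P450 that activates AOM, was below the expression filter. Of 22 genes of fatty acid oxidation and ketogenesis 19 fell and none rose, with a median of -0.86, and 21 fell with medians subtracted; the carnitine carrier Slc25a20 fell by 1.73 (SE 0.26). Of 28 oxidative phosphorylation genes 25 fell, with a median of -0.52, and 27 fell with medians subtracted. The cytochrome c oxidase subunits Cox5b and Cox6c fell by 0.89 (SE 0.08) and 0.89 (SE 0.06), while Ndufa4 rose by 0.92 (SE 0.13). Of 22 glycolysis and hypoxia genes 5 rose and 8 fell; with medians subtracted 2 rose and 13 fell. The lactate carrier Slc16a3 and the regulator Pfkfb3 rose by 1.66 (SE 0.34) and 1.13 (SE 0.14), and the hexokinase Hk1 and Car9, a hypoxia target, fell by 1.23 (SE 0.13) and 1.22 (SE 0.36). Of 16 immediate early genes 5 rose and 5 fell (4 and 7 with medians subtracted), Cyr61 and Ier3 by 2.02 (SE 0.23) and 1.84 (SE 0.30) upward and Klf4 and Klf6 by -2.94 (SE 0.33) and -0.97 (SE 0.25). Of 18 heat shock and unfolded protein response genes 6 rose and 3 fell (5 and 5 with medians subtracted); the chaperones Hspb1 and Hsph1 rose by 2.89 (SE 0.38) and 1.35 (SE 0.24), and Herpud1 and Dnajb9 fell by 0.83 (SE 0.17) and 0.51 (SE 0.15).

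**Figure D2:**
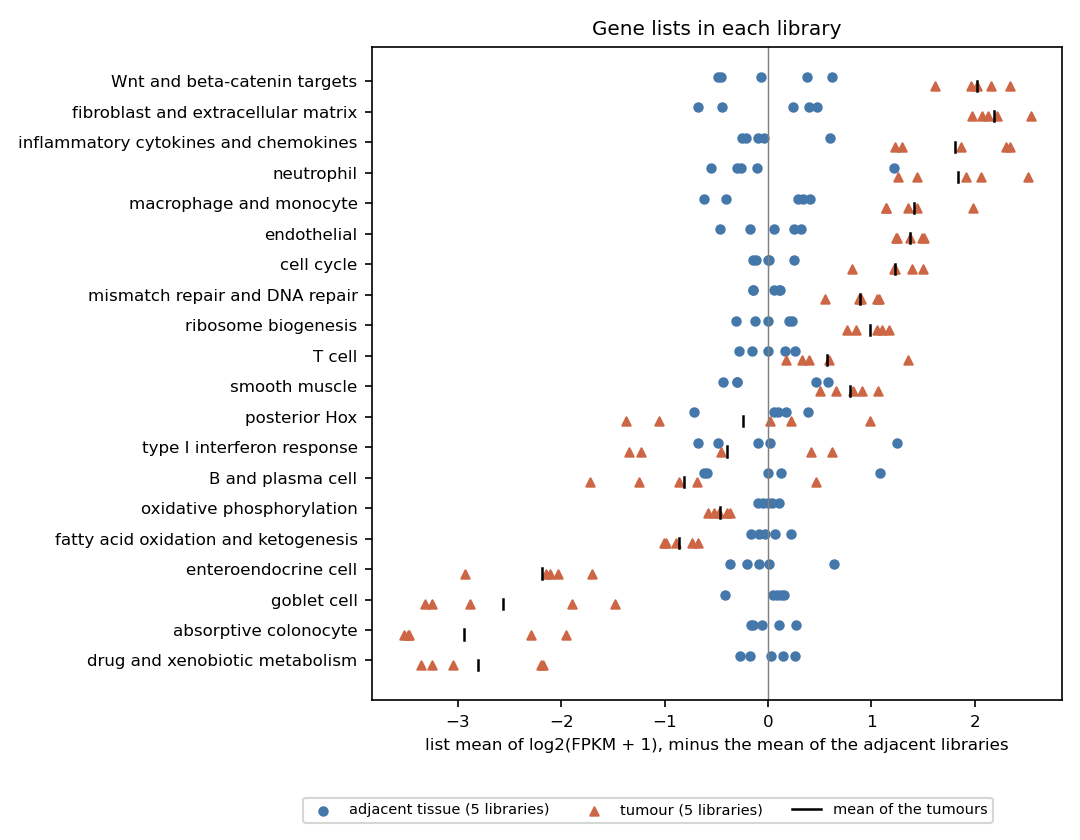
Mean of log2(FPKM + 1) over the tested genes of 20 gene lists in each library, minus the mean of the 5 adjacent samples, with circles for adjacent samples, triangles for tumours and a bar at the tumour mean. All 5 tumours lie above all 5 adjacent samples for Wnt targets and below them for absorptive colonocyte genes, whose median log2 changes were 2.11 and -2.91, while the groups overlap for posterior Hox and interferon genes.

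Of 22 colorectal cancer driver genes 13 rose and 4 fell; with medians subtracted 8 rose and 8 fell. Rnf43, a Wnt receptor ligase, rose by 2.08 (SE 0.25), and Trp53, the p53 tumour suppressor, from 28.8 ± 5.99 to 79.7 ± 12.5 FPKM (n = 5 per group). Erbb3 and Tcf7l2 fell by 1.19 (SE 0.13) and 0.97 (SE 0.13), and Smad4 by 0.39 (SE 0.10). Ctnnb1, beta-catenin, rose from 359 ± 18.3 to 528 ± 53.9 FPKM, a log2 change of 0.55 (SE 0.08). The change was 0.22 with medians subtracted (limma adjusted p = 0.0232) and 0.77 with quantile normalization (limma adjusted p = 4.52e-05). Apc, the scaffold of the beta-catenin destruction complex (chromosome 18, 34220924 to 34322552), was at 13.7 ± 0.51 FPKM in adjacent tissue and 11.1 ± 4.41 FPKM in tumours, a log2 change of -0.37 (SE 0.23, limma adjusted p = 0.166). It passed with medians subtracted (-0.70, adjusted p = 0.024), with quantile normalization (-0.70, adjusted p = 0.0325) and without tumours 2 and 4 together (-0.60, adjusted p = 0.0489). The tumours were not alike: Apc was at 6.27 FPKM in tumour 3 and 6.48 FPKM in tumour 5, and at 13.3 to 15.7 FPKM in the other 3.

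Of 9 posterior Hox genes, which mark position along the body axis, Hoxa10 rose by 0.43 (SE 0.18) and Hoxa13 fell by 0.49 (SE 0.18), with none past the threshold when adjusted over the list alone. The Hoxa10 call was lost with medians subtracted (0.10, adjusted p = 0.644), with the replicate block (adjusted p = 0.0762) and without any one of the libraries but adjacent sample 1 and tumours 1 and 4 (adjusted p from 0.0655 to 0.104). That of Hoxa13 was lost without any one of adjacent sample 4 or tumours 3, 4 and 5 (0.0533 to 0.0619), while its log2 change was -0.82 with medians subtracted (adjusted p = 0.00343) and -0.76 with quantile normalization (adjusted p = 0.00701). Hoxb13 was at 13.8 FPKM in tumour 2, against 134 to 298 FPKM in the other 9 libraries. Hoxd13 was at 0.14 FPKM in tumour 2 and 1.01 FPKM in tumour 5, at 82.3 FPKM in tumour 1, and at 4.13 FPKM in adjacent sample 1.

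**Figure D3:**
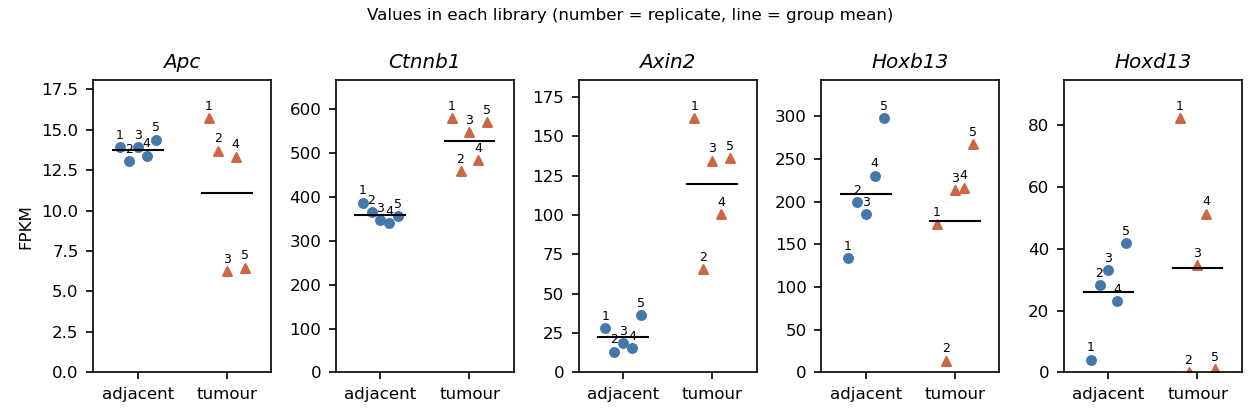
FPKM of Apc, Ctnnb1, Axin2, Hoxb13 and Hoxd13 in each library on linear axes from 0, with circles for 5 adjacent samples, triangles for 5 tumours, replicate numbers beside the points and a line at each group mean. Axin2 is higher in each tumour than in each adjacent sample, while Apc lies at 6.27 and 6.48 FPKM in tumours 3 and 5 and Hoxb13 at 13.8 FPKM in tumour 2.

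With camera at a preset correlation, 20 of 41 lists passed an adjusted p of 0.05, and none did with an estimated correlation. The absorptive colonocyte list had an adjusted p of 4.42e-14, as did the oxidative phosphorylation and drug metabolism lists. With an estimated correlation the lowest adjusted p was 0.246, shared by the absorptive colonocyte, enteroendocrine, proximal identity, fatty acid oxidation and drug metabolism lists; for oxidative phosphorylation the adjusted p was 0.351 with an estimated correlation. For the Wnt target list these were 0.000202 and 0.647, the latter an adjusted p with an estimated correlation. The counts of genes given for each list, adjusted over all genes tested, were the same when adjusted over the list alone except for the tuft cell, B and plasma cell, mast cell, posterior Hox, type I interferon, and heat shock lists. In the tuft cell list 3 then rose, and in the heat shock list 2 then fell. The Paneth-like, mast cell, red blood cell, class II, immediate early and heat shock lists had a median above 0 and a camera direction of down, none past the threshold. The tuft cell list had a median of -0.03 and a mean of 0.35, and the adipocyte list a median of 0.02 and a mean of -0.90.

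The spread between tumours was compared with that between adjacent samples. The median gene had an SD of 0.187 in tumours and 0.159 in adjacent tissue on the log2(FPKM + 1) scale, and the median log2 ratio of the SDs was 0.25 (n = 5 per group, two-sided exact permutation p = 0.579). The difference did not pass, and without tumour 2 the ratio was -0.14 (exact permutation p = 0.437). With quantile normalization it was 0.48 and passed (exact permutation p = 0.0397).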

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

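Of 156 groups of 5 values examined, 12 held a library whose gap to the nearest other exceeded Dixon's 95% limit, where chance gives about 1 in 20, or 7.8. Values here are log2(FPKM + 1), for lists the mean over tested genes. The tests on tumour 2 and on Apc, and the condition added to the test with 1000 genes left out, were chosen after the result was seen. Adjacent sample 5 held 6 of the 12. It was high in Alox12 at 3.46 (1.46 to 1.71 in the other 4), in Lcn2 at 5.67 (3.38 to 3.99), in inflammatory cytokines and chemokines at 2.42 (1.58 to 1.78), in neutrophil genes at 2.49 (0.72 to 1.16) and in red blood cell genes at 5.02 (2.38 to 2.63), and low in goblet cell genes at 8.11 (8.57 to 8.68). Tumour 4 was high in Sycn at 6.01 (2.71 to 3.40 in the other 4 tumours), Hao2 at 4.05 (1.48 to 1.65) and Zg16 at 9.81 (6.44 to 7.10). Tumour 2 was low in Alox12 at 3.50 (5.63 to 6.04) and in Trp53 at 5.89 (6.33 to 6.48). Tumour 1 was low in genes of small-intestinal and proximal identity at 1.95 (2.33 to 2.47).

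Tumour 2 lay between the other tumours and adjacent tissue on the first principal component, at 28.1. On the second, which held 7.3% of the variance, it lay at -44, outside the range of -8.3 to 15.2 in the other libraries. Adjacent mucosa in the piece taken as tumour 2 was tested on genes chosen from the other 4 tumours: the 209 rising genes would need a median share of 49.3% adjacent tissue (quartiles 22.8% and 66.3%), and the 118 falling genes would allow 15.7% (6.4% and 34.4%). The quartiles overlap, so by them the test did not decide. A share of 22.8% of tissue like these adjacent samples would hold each falling gene at or above 22.8% of its adjacent level. Yet 50.8% of the falling genes lay below 22.8% of their lowest adjacent sample. For these genes, this argues against a share of that size or more in tumour 2. A smaller share cannot be told apart from a difference in the site or stage of the tumour, which was not tested. The falling genes were not alike: Car4, Aqp8, Cyp2c55, Zg16 and Clca1 were at 1%, 1.5%, 1.3%, 3% and 8.5% of their adjacent mean in tumour 2, but Muc2, Tff3, Lypd8 and Ceacam1 at 35.4%, 36.5%, 47.8% and 70.9%. For tumour 4 the 108 falling genes would allow 16.5% (quartiles 11.1% and 21.4%) and the 183 rising genes would need 5% (-10.1% and 22.9%), so a share of adjacent tissue was not excluded there either.

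Apc was at 6.27 and 6.48 FPKM in tumours 3 and 5 and at 13.07 to 15.71 FPKM in the other 8 libraries. Of 3252 genes of like expression, 6.33% and 6.83% were as far below their adjacent mean in these tumours. Loss of a chromosome 18 segment would lower its neighbours. Set against their adjacent means, 62 genes within 5 Mb had median log2 deviations of 0.37 and 0.31 in tumours 3 and 5. Apc was at -1.02 and -0.98, below these medians by at least 1.29. Loss of a smaller segment around Apc could leave such a median unchanged and was not tested. Poor depth or scaling of these 2 libraries would lower genes of like expression, but their medians were 0.43 and 0.42, above Apc by at least 1.4. A candidate explanation is a loss confined to Apc, such as a deletion or a truncating mutation with decay of the transcript, which these values cannot test and for which the labels give no genotype.

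The median tested gene was 0.35 higher in tumours. If a few abundant genes took the FPKM total in adjacent tissue, leaving out its 20 most abundant genes and rescaling would remove most of this, but 0.3 remained. With 1000 left out 0.11 remained, but ranking on adjacent tissue favours genes that are higher there, and with the 1000 most abundant over all libraries left out 0.21 remained. Whether many abundant genes set the shift therefore cannot be told apart from a true change in most genes, which FPKM cannot show. Gene length bias was argued against by the longest and shortest genes in 3 equal sets by transcript length, whose medians differed by 0.03.

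In 100 of the 126 splits of the 10 libraries into 5 and 5, only the real one, 1 of 100, gave as many genes. This argues against an arbitrary split of these libraries as the source of the gene counts. It does not exclude chance differences between animals, since the labels do not settle which libraries share an animal. The real split called 9951 genes against at most 4260 in another; 7442 against 3302 in the larger direction, 2509 against 1080 in the smaller, and 3030 against 1294 with a 2-fold change. For the number of gene lists past the threshold, 41 of the 100 splits gave 20 lists or more, up to 26. Each split but the real one holds unequal numbers of tumours and adjacent samples on its sides, and so keeps part of the group contrast. The count of lists therefore cannot decide on chance, and no conclusion is drawn from it.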

How the results depend on the processing

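Median subtraction and leaving out tumours 2 and 4 together were chosen after seeing the data; the other settings were planned. The count of called genes stayed within 1.5 times of 9951 in all settings run, but the number of genes tested differed. It was 7522 of 9736 tested with a mean of at least 5 FPKM and 11708 of 19733 with no filter, against 9951 of 13016. Without 1 library the count ranged from 9423 to 10230 (7063 to 7625 higher, 2324 to 2605 lower, 2809 to 3333 changed 2-fold). With a pseudocount of 5 the 2-fold count was 1406, since a larger pseudocount shrinks the change of low genes. Quantile normalization gave 4759 higher and 3934 lower genes, and median subtraction 4486 and 4329; of the 9951 calls, 2698 and 2903 were lost, 900 and 946 changed sign, and 72 and 53 were called in the other direction. The list count was 20 with camera, 18 to 21 without 1 library, and 0 with an estimated correlation (the cause was not tested). The log2 ratio of spreads ranged from -0.14 to 0.41 without 1 library and was negative only without tumour 2; it was 0.48 with quantile normalization (the cause was not tested). Without tumours 2 and 4 together, Cd74 was at -0.17 and H2-Ab1 at -0.2, both uncalled in every setting, and 10106 genes were called. The fit without pairs was fixed beforehand, since the labels state no paired model. The like-numbered libraries deviated together with correlations of 0.02, 0.32, 0.02, 0.16 and 0.42, and 2 of 5 correlated best with their own number. These values do not settle whether the numbers pair the samples. The replicate block called 10067 genes, and 9283 to 9835 without 1 pair. Over 125 named genes and their settings, 2714 of 2859 values kept direction and side of the threshold, 134 no longer passed, 9 newly passed and 2 changed sign. The macrophage list lost its camera call with the replicate block (adjusted p = 0.11) and without tumour 2 (0.078), and the neutrophil list lost its call without adjacent 1, 2 or 3 or tumour 2 or 5 (0.0502 to 0.068). The interferon list lost its call without adjacent 2 (0.107) or tumour 5 (0.0574), with quantile normalization (0.165), median subtraction (0.226) and fry (0.644); the glycolysis list without adjacent 5 (0.0564), with quantile normalization (0.629) and fry (0.364); and the B and plasma cell list with quantile normalization, median subtraction and fry (0.0776, 0.119 and 0.203). With quantile normalization and median subtraction the TGF-beta (0.0053, 0.0076), fetal-like (0.0226, 0.0475) and translation factor (0.000482, 0.0397) lists newly passed. With no filter 24 lists passed, newly the tuft cell (0.0229), pancreatic acinar (0.0029), TGF-beta (0.0268) and translation factor (0.00911) lists. With fry, which tests for a shift from no change and not against other genes, 27 lists passed: 10 newly, such as the intestinal stem cell (0.000317), TGF-beta (2.97e-05) and squamous (0.000451) lists, while 3 were lost. RLE, upper-quartile and total-count scaling, DESeq2, voom and the CPM filter were not run, since the table holds no counts. What depth limits was not tested, since the depth is only an estimate.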

Other observations

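The families here were all chosen after their values were seen, and some members, such as Col1a1 and Ptgs1, are also in the fixed lists. With camera no family passed with an estimated correlation (lowest adjusted p = 0.0985). Of 25 collagen genes 23 rose and none fell, with a median log2 change of 1.94, and 22 rose with library medians subtracted. Of 8 Wnt ligand genes 7 rose and none fell (5 with medians subtracted); Wnt10a rose by 2.81 (SE 0.38), Wnt5a by 2.45 (SE 0.26) and Wnt6 by 2.39 (SE 0.30). Of 26 nuclear receptor genes 17 fell and 5 rose (20 and 3 with medians subtracted). Vdr, the vitamin D receptor, fell from 80.8 ± 13.7 to 8.96 ± 3.27 FPKM (n = 5 per group), Nr5a2 by 2.58 (SE 0.18), and the bile acid receptor gene Nr1h4 by 2.54 (SE 0.41), while Rarb, a retinoic acid receptor, rose by 2.16 (SE 0.54). Of 77 ribosomal protein genes 59 rose and none fell, but with medians subtracted 6 rose and 6 fell.

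Of 12 genes of prostaglandin synthesis, breakdown, transport and reception 5 rose and 3 fell (5 and 6 with medians subtracted). Ptgs2, cyclooxygenase 2, rose by 2.41 (SE 0.37) and Ptges, a prostaglandin E synthase, by 1.43 (SE 0.19), while Hpgd, which inactivates prostaglandins, fell from 74.2 ± 9.24 to 10.5 ± 2.28 FPKM. Of 11 claudin genes, which encode proteins of cell junctions, 6 fell and 4 rose. Cldn8 and Cldn15 fell by 2.71 (SE 0.39) and 2.18 (SE 0.46), and Cldn4 rose by 1.56 (SE 0.19). Of 6 UDP-glucuronosyltransferase genes 5 fell. Of 238 tested solute carrier genes 92 rose and 89 fell (59 and 128 with medians subtracted); Slc30a2 and Slc7a11 rose by 2.85 (SE 0.38) and 2.19 (SE 0.42), while Slc13a2 and Slc5a8, which take up carboxylates, fell by 4.39 (SE 0.49) and 4.07 (SE 0.40).

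The Hoxd genes differed between single libraries far more than between groups. Hoxd10, Hoxd11 and Hoxd13 were at 0, 0.04 and 0.14 FPKM in tumour 2 and at 0.09, 0.12 and 1.01 FPKM in tumour 5. They were at 10.98, 15.01 and 82.35 FPKM in tumour 1, and at 0.66, 0.64 and 4.13 FPKM in adjacent sample 1. Hoxd12 was at 15.89 FPKM in tumour 1 and at most 1.77 FPKM in the other 9 libraries. Hoxb13 was at 13.79 FPKM in tumour 2 and at 267.44 FPKM in tumour 5, so the 2 tumours with the lowest Hoxd13 differed in it.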
